A study of Oryza sativa with 475 samples.

How the data were processed

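Gene expression was measured by RNA sequencing in leaves of rice plants grown in liquid culture at 30 °C. The 475 libraries cover 4 genotypes (Azuenca, AZ, and Pandan wangi, PW, both japonica, and Kinandang puti, KP, and Tadukan, TD, both indica), 5 treatments and sampling times 15 min apart at their closest, in 240 groups of genotype, treatment and time. Per the labels' protocols, total RNA was depleted of ribosomal RNA, libraries were made with a ScriptSeq v2 kit, and 51 bp paired-end reads were taken. The groups hold 2 libraries each in most cases, and the series description calls them biological replicates.

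The authors deposited a single table of log2 values for 56143 loci in all 475 libraries. Per the submitters' processing notes, TopHat2 2.0.6, HTSeq 0.6.1 and DESeq2 1.6.3 were used, without a stated role for each. The genome build, the annotation and whether counting used strand are not given in the sources used here. The deposited log2 values have the form of a variance-stabilising transform of counts divided by a size factor. A count of 0 stands at 1.86, and inverting the transform gave whole counts for 100% of 26667925 values, within a tolerance of 0.001. In such a scale high values behave as log2 counts and low values are compressed towards the floor, so fold changes of weakly expressed loci are understated. Recovered totals ran from 784787 to 38337716 counts per library with a median of 7286730, and 57.8% of values were a count of 0. Normalised counts printed in the text are the recovered counts divided by the recovered size factors.

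Loci are given as identifiers in the table, and 0 of them were found among the identifiers and symbols of the reference gene table (assembly ASM3414082v1), so no gene is named. The rule fixed for named genes, which required a name in the files or reference, therefore took no gene. In its place at most 2 identifiers that were higher and 2 that were lower are printed for heat and for dehydration, chosen by the rest of that rule: the largest fold changes among called loci with the same sign in 4 genotypes and a mean at or above the median of tested loci. Of the gene lists fixed before the data were examined, those defined by gene descriptions could not be matched. The 7 lists written as locus identifiers were used: heat stress transcription factors, small heat shock proteins, DREB transcription factors, clade A protein phosphatases 2C, abscisic acid synthesis and breakdown, LEA proteins and dehydrins, and the circadian clock. Their membership was written from general knowledge of rice gene families and rests on it.

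The 2 AZ control libraries at 225 min whose titles share a number had counts that differed by little more than sampling noise (chi-square per degree of freedom 1.14, against 13.6 and 12.9 with the other library of the group). They were averaged and counted as 1 sample, which left 474 samples. Loci with a mean normalised count of at least 10 over all libraries were tested (17665 loci). limma 3.58.1 in R 4.3.3 was run on the deposited values with 1 mean for each of the 240 groups, which left 234 residual degrees of freedom, and with an intensity trend in the variance prior. Each comparison was the average, over genotypes and matched times, of the difference between 2 treatments. A locus was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. Differences between genotypes and changes over control times were tested with a moderated F test and a range of at least 1. Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the 7 lists of a comparison. The plan allowed for count tests, but the deposited unit is log2, so the test planned for log2 values was the one applied.

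The labels give no replicate numbers, so no library of one group is paired with a library of another. Title numbers, however, were divided into 2 ranges, separately for the control and dehydration libraries and for the heat libraries. These are called here the first series (223 libraries) and the second series (211 libraries). In the control and dehydration libraries the 2 ranges adjoin. 41 libraries were placed in neither, because the title lies outside both ranges or because 2 libraries of a group fell in the same range. The ranges of the heat and heat recovery libraries are not those of the control and dehydration libraries. A comparison of heat or heat recovery with control, or of heat with dehydration, therefore spans different ranges. This holds within a series and, but for few libraries, over all libraries. A difference between runs that the ranges follow cannot be told apart from heat in these comparisons. The series are used to recompute results within each and to compare replicate libraries, and they were defined after library responses had been seen to split. Whether libraries of a series shared a growth or treatment run is not given. If they did, p-values over libraries are too small.

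The tests were checked on simulated data drawn from the loci's real means and the real size factors, with 200 of 17665 loci changed. Counts were drawn independently, with a dispersion of 0.2 for each locus and no difference between series or runs. The shares therefore do not give the error rate where libraries share a run. For heat vs control, 100% of 66 loci with a 4-fold change and 83.6% of 67 with a 2.5-fold change were called, 0 of 67 with a 1.5-fold change were called, and 0 unchanged loci were called. For dehydration vs control the shares were 98.5% and 82.1%, for the heat response by genotype 98.5% and 91%, and for time in control 100% and 95.5%, with 8 unchanged loci called in the last. Alternatives in filtering, scaling, transform, test, threshold, libraries, times and genotypes were recomputed, and labels were exchanged at random in 100 regroupings per comparison. For the responses by genotype, each genotype's control mean was subtracted before the exchange, a step added after a first run without it had been seen. Both runs are given with the results. For japonica against indica whole genotypes were exchanged, since the subspecies is set by genotype. The exchange of single libraries planned there had been run and seen first, and is not used.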

Results

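Leaf transcripts of 4 rice genotypes were followed through heat and through loss of water at the roots, and through return from each. Control plants stayed at 30 °C in liquid medium (143 libraries). Heat plants were moved to 40 °C (128 libraries), and heat recovery plants were moved back after 120 min (63 libraries). Dehydration plants had their roots in air (71 libraries), and dehydration recovery plants had them returned to medium after 90 min (70 libraries). AZ, PW, KP and TD had 119, 118, 118 and 120 libraries. Total counts per library had medians of 7536098 in control, 6571038 in heat, 7445508 in heat recovery, 6771812 in dehydration and 8180226 in dehydration recovery, within an overall range from 784787 to 38337716. A pair of AZ control libraries at 225 min differed by little more than sampling noise and was counted as 1 sample.

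The first comparison asked which transcripts heat changed. Small heat shock proteins, chaperones that bind unfolding proteins, rose most. 14 of 15 measured members were higher in heat than in control over the 16 matched times, also when adjusted over the list alone, and the list mean rose by 4.89 ± 0.18 on the log2 scale (SD over 4 genotypes). LOC_Os03g14180, a member of that list, had a log2 fold change of 8.49 with an SE of 0.105 and a limma adjusted p of 7.74e-172. Its mean was 3855 ± 3260 normalised counts in heat (SD, n = 128) and 4.15 ± 8.22 in control (SD, n = 126). Such means are arithmetic means over libraries, and a fold change is an average of group differences on the deposited log2 scale, so the ratio of the means does not give the fold change. LOC_Os01g04370, another member, had a log2 fold change of 8.31 (SE 0.096), between 8.18 and 8.37 in the 4 genotypes. The small heat shock proteins include near-identical neighbours that could share reads, so the split between members is uncertain.

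Of 18 measured heat stress transcription factors, the regulators of heat shock genes, 4 were higher and 0 were lower, with a median log2 fold change of 0.36 and a highest of 3.22. Among 5 LEA proteins and dehydrins, which accumulate in drying tissue, 4 were higher, with a median of 1.39. The list tests gave camera adjusted p of 3.65e-35 for small heat shock proteins, 0.000732 for heat stress factors and 0.0359 for LEA proteins. With an estimated correlation the adjusted p was 2.79e-07 for small heat shock proteins, 0.195 for heat stress factors and 0.384 for LEA proteins. The clade A phosphatases 2C, which hold back abscisic acid signalling, had 1 of 7 members higher, abscisic acid metabolism had 1 of 6, and DREB and clock lists had 0 members called, and none of these 4 lists passed (adjusted p 0.184, 0.514, 0.322 and 0.184). Counts adjusted over the list alone were the same for each list in this comparison.

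Over all loci, limma called 464 of 17665 in heat against control, 289 higher and 175 lower. An adjusted p under 0.05 alone called 6186 higher and 7064 lower. LOC_Os03g19427 fell by 4.25 on the log2 scale (SE 0.289, limma adjusted p 3.75e-34). Its arithmetic mean was 1751 ± 1925 normalised counts over the control libraries and 304.2 ± 829 over the heat libraries. LOC_Os01g45914 fell by 3.73 (SE 0.347). The called loci had mean responses in the direction of the comparison of 1.75 in AZ, 1.77 in PW, 1.64 in KP and 1.64 in TD. Within the first series of title numbers 614 loci were called, and within the second 424, with heat and control libraries from different number ranges in each.

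More loci were called in heat at 15 min than at any later time. At 15 min 1006 loci were higher and 742 lower than control (8 libraries against 8), at 60 min 436 and 281, and at 195 min 142 and 147. The decline was not steady, with 748 loci called at 150 min and 650 at 240 min, the times with 7 control libraries. Heat recovery against the same control libraries also went from 126 loci at 225 min to 732 at 240 min. Dehydration recovery did not rise there, with 539 at 210 min and 357 at 240 min. The rise in heat at 240 min can lie in the shared controls and cannot be assigned to heat. That time is part of the late window below. The small heat shock protein mean fell from 7.43 ± 0.34 at 15 min to 4.44 ± 0.39 at 120 min and 2.59 ± 0.40 at 240 min (SD over 4 genotypes). The heat stress factor mean fell from 2.39 ± 0.12 at 15 min to 0.75 ± 0.20 at 60 min and was -0.02 ± 0.19 at 240 min. In the test of late (195 to 240 min) against early (15 to 60 min) heat response, 523 loci were called, of which 487 had a smaller value late. That direction depended on the fold threshold, since an adjusted p alone called 3419 with a higher value late and 2818 with a lower one. 14 of 15 small heat shock proteins and 9 of 18 heat stress factors were lower late, with camera adjusted p of 5.75e-46 and 1.73e-14, and of 3.03e-09 and 0.000232 with an estimated correlation. Of the 289 loci higher in heat, 182 were called smaller late and 2 larger late, and of the 175 lower loci 3 were called closer to control late and 2 further from it.

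**Figure D1:**
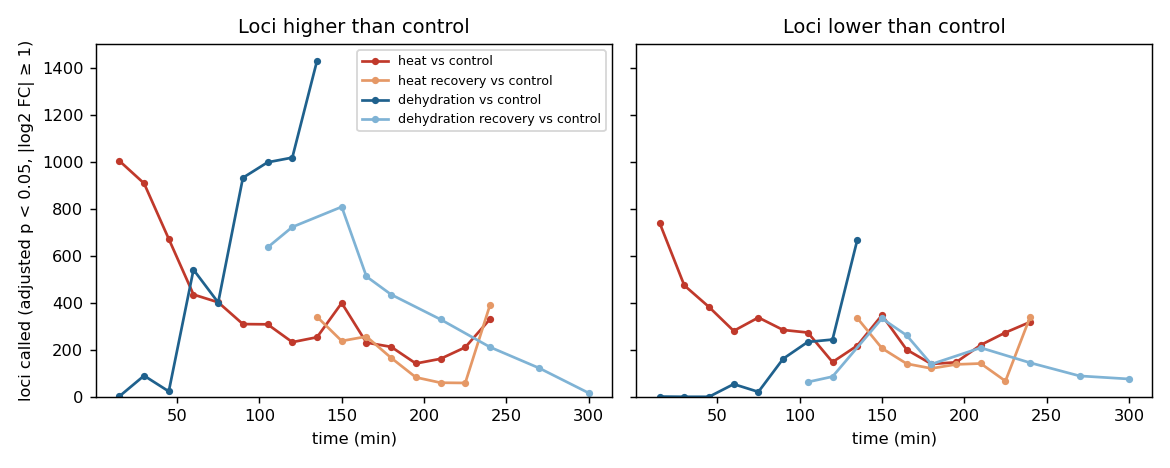
Loci called higher (left) or lower (right) than control at each time in minutes, averaged over 4 genotypes, for heat, heat recovery, dehydration and dehydration recovery. Heat peaks at 15 min with 1006 higher loci, and dehydration reaches 1433 higher loci at 135 min.

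Recovery from heat was compared with continued heat and with control at 135 to 240 min. Heat stress factors fell on return to 30 °C: 4 of 18 were lower than in continued heat and 0 higher, and the list mean was lower by 0.48 ± 0.07 (camera adjusted p 5.95e-06, and 0.079 with an estimated correlation). Small heat shock proteins stayed above control, with 13 of 15 members higher, a mean of 3.29 ± 0.21 and a camera adjusted p of 1.45e-39 (4.32e-08 with an estimated correlation). Against continued heat 2 of 15 were lower, with a list mean of -0.33 ± 0.09 that did not pass (adjusted p 0.137). Heat stress factors stood at a mean of -0.20 ± 0.16 against control, with 1 member higher, 1 lower and a camera adjusted p of 0.00273, lost with an estimated correlation (adjusted p = 0.289). The other 5 lists passed neither test (adjusted p 0.16 to 0.935 against continued heat and 0.431 to 0.553 against control), with 1 phosphatase called higher than control.

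limma called 140 loci between heat recovery and continued heat, 32 higher and 108 lower, and 240 between heat recovery and control, 98 higher and 142 lower. An adjusted p alone called more loci higher than lower in both, 5365 against 4475 and 5432 against 5079. Of 474 loci higher in heat at 15 to 120 min, 53 (11.2%) were still higher in recovery and 10 were lower than control. Of 228 loci lower in heat at those times, 85 (37.3%) were still lower. Against continued heat at the recovery times, 75 of the 474 were called lower and 7 of the 228 higher, so for the others a return beyond that seen in continued heat was not called. The median fold changes were 1.42 and -1.23 in heat and 0.25 and -0.74 in recovery. The sets were defined on earlier libraries than those of the recovery comparison. Within the first series 187 loci were called between recovery and continued heat and within the second 173.

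The next comparison asked which transcripts loss of water at the roots changed. Of 7 clade A phosphatases 2C, 6 were higher over the 9 matched times, with a mean of 2.08 ± 0.55 (SD over 4 genotypes). 3 of 6 genes of abscisic acid synthesis and breakdown were higher, with a highest log2 fold change of 4.66, and 5 of 5 LEA proteins and dehydrins were higher, with a median of 1.73. 3 of 18 heat stress factors and 2 of 5 DREB factors were higher. The small heat shock proteins and the clock genes had 0 members called, with list means of 0.18 ± 0.21 and 0.10 ± 0.05. No listed gene was called lower, and counts adjusted over the list alone were the same.

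Camera adjusted p were 3.04e-15 for the phosphatases, 6.41e-07 for abscisic acid metabolism, 1.16e-06 for heat stress factors, 3.95e-05 for LEA proteins and 0.0154 for DREB factors. With an estimated correlation they were 0.000724, 0.00407, 0.0226, 0.0565 and 0.113. The small heat shock proteins and clock had adjusted p of 0.397 and 0.753. The LEA proteins and dehydrins contain a cluster of similar neighbours whose reads could be shared.

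Over all loci 447 were called in dehydration against control, 431 higher and 16 lower. That split depended on the fold threshold, since an adjusted p under 0.05 alone called 4874 higher and 5310 lower. LOC_Os02g43330 rose by 4.78 on the log2 scale (SE 0.238, limma adjusted p 3.49e-50). Its arithmetic mean was 27.5 ± 35.6 normalised counts over control libraries (SD, n = 72) and 2941 ± 4099 over dehydration libraries (SD, n = 71). LOC_Os07g05940, of the abscisic acid list, rose by 4.66 (SE 0.238), between 3.13 and 6.01 in the 4 genotypes. LOC_Os03g18600 fell by 1.88 (SE 0.096) and LOC_Os10g34230 fell by 1.12 (SE 0.101). Within the first series 342 loci were called and within the second 679.

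More loci were called late in dehydration than early, though not at each step. At 15 min 3 loci were called, at 30 min 90, at 45 min 23, at 60 min 596, at 75 min 423, at 90 min 1096 and at 135 min 2101, of which 1433 were higher and 668 lower. The phosphatase mean was 0.36 ± 0.18 at 15 min, 2.51 ± 0.88 at 60 min, 3.35 ± 0.63 at 120 min and 2.47 ± 0.72 at 135 min. The LEA and dehydrin mean was -0.37 ± 0.06 at 15 min, 1.41 ± 0.57 at 60 min and 4.00 ± 2.07 at 90 min. In the test of late (90 to 135 min) against early (15 to 60 min) response 889 loci were called, 706 with a higher value late and 183 with a lower one (4332 and 4572 under an adjusted p alone), and 316 of the 431 higher loci were larger late. 6 of 7 phosphatases and 5 of 5 LEA genes were higher late (camera adjusted p 1.16e-07 and 5.82e-06, and 0.0461 and 0.0547 with an estimated correlation).

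**Figure D2:**
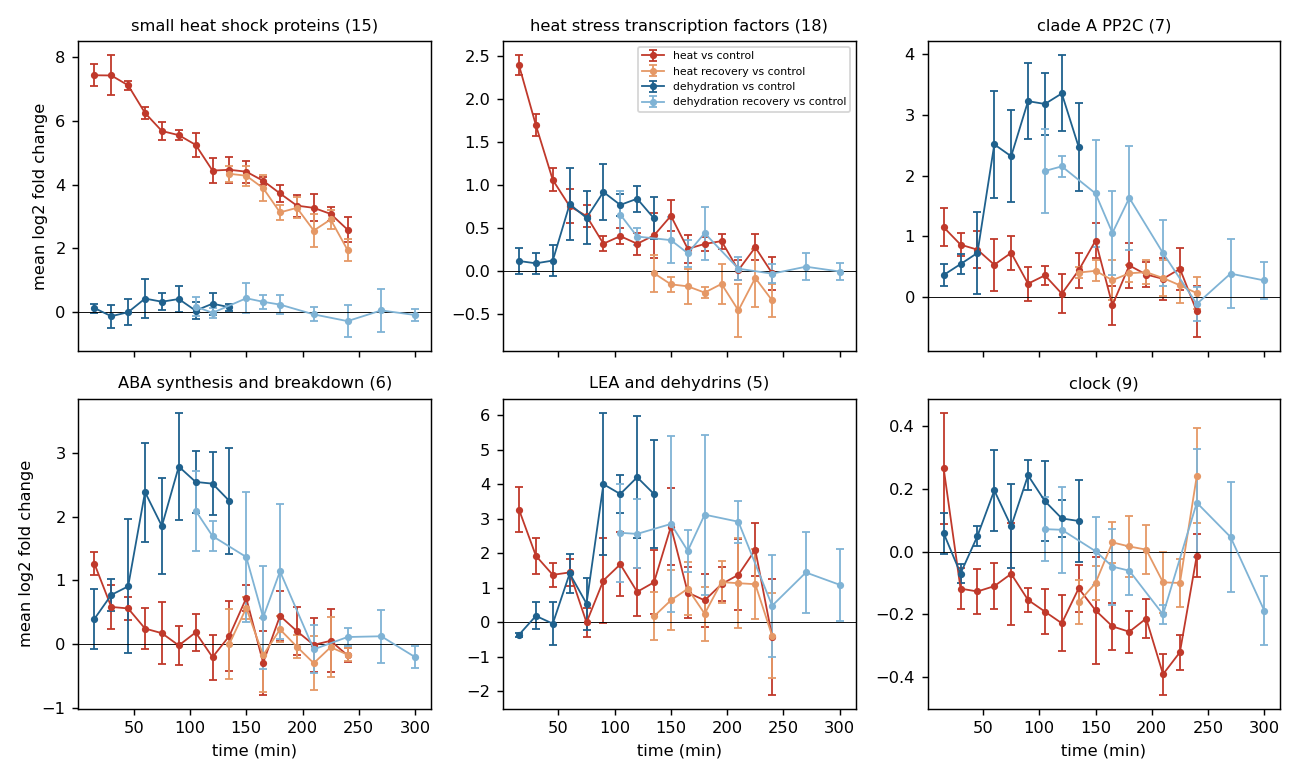
Mean log2 fold change against control of the members of 6 gene lists (number of members in brackets) by time in minutes. Points are means and bars SDs over 4 genotypes, and colours mark the 4 stress treatments. Small heat shock proteins start at 7.43 in heat and stay near 0 in dehydration, whereas clade A phosphatases 2C reach 3.35 in dehydration.

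On return of the roots to medium, the phosphatases fell. At 105 and 120 min 5 of 7 were lower than in continued dehydration, with a list mean lower by 1.15 ± 0.44 (camera adjusted p 3.35e-09, and 0.0194 with an estimated correlation). LEA proteins and dehydrins had 2 of 5 members lower, or 4 of 5 adjusted over the list alone (camera adjusted p 0.00163, and 0.222 with an estimated correlation), and heat stress factors 2 of 18 (0.00289 and 0.222). Abscisic acid metabolism had 2 members lower and 1 higher and did not pass (adjusted p 0.0943), nor did the other 3 lists (0.603 to 0.831), with 1 DREB factor called higher. limma called 278 loci, 98 higher and 180 lower. The split between higher and lower, 35.3% higher, was not stable: 58.4% of calls were higher without the first library of each group and 23.8% without the last, 52.5% without PW, and 72.5% of 120 without libraries whose titles carry a suffix, which left 6 of the 8 pairs of genotype and time. Within the first series 33.7% of 205 were higher, and the second gave no value.

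Against control over 105 to 300 min, 273 loci were called in dehydration recovery, 237 higher and 36 lower. 5 of 5 LEA proteins and dehydrins were higher with a median of 2.38, and 5 of 7 phosphatases were higher with a median of 1.34. Both lists had a camera adjusted p of 7.07e-05, and of 0.117 with an estimated correlation. Abscisic acid metabolism had 1 of 6 members higher (0.0342, and 0.292 with an estimated correlation). The other 4 lists did not pass (adjusted p 0.0692 to 0.694), with 1 heat stress factor and 1 DREB factor called higher. The number of called loci was 700 at 105 min, 810 at 120 min and 1144 at 150 min, a time with 7 control libraries. It then fell to 92 at 300 min. Of 229 loci higher in dehydration at 15 to 90 min, 85 were called higher in recovery over all times, 97 were called lower than in continued dehydration, and 1 was still higher at 300 min, where their median was -0.13. The phosphatase mean was 0.27 ± 0.31 at 300 min and the LEA and dehydrin mean 1.08 ± 1.05. Within the first series 231 loci were called and within the second 664, without AZ 165 were called, and without the first library of each group 463.

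Heat and dehydration were set side by side at 15 to 135 min, with no control library in the comparison. 14 of 15 small heat shock proteins were higher in heat (mean 5.77) and 6 of 7 phosphatases were higher in dehydration (mean -1.51, heat minus dehydration). 3 of 6 abscisic acid genes, 2 of 5 DREB factors and 1 of 5 LEA genes were also called higher in dehydration, and 5 of 18 heat stress factors were called higher in heat. Camera adjusted p were 1.05e-36 for small heat shock proteins, 4.75e-05 for phosphatases and 0.0181 for abscisic acid metabolism, and 1.45e-07, 0.125 and 0.221 with an estimated correlation. The heat stress factor, DREB, LEA and clock lists did not pass (adjusted p 0.229, 0.431, 0.431 and 0.346), and the DREB median of 0.16 and mean of -0.49 differed in sign. limma called 981 loci, 358 higher in heat and 623 higher in dehydration. At a log2 fold change of at least 2 the split turned, with 89 higher in heat and 57 higher in dehydration.

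Fold changes of the 2 stresses against the shared control libraries had a Pearson r of 0.236 across loci, which are not independent replicates. Unchanged groups simulated against these controls gave 0.499, with a covariance of 0.00223 against an observed 0.0426. With controls split between the comparisons r was 0.230 and the covariance 0.0407. Without the first library of each group r was 0.149 and without the last 0.282. Within the first series r was 0.278 and within the second 0.150. The first library of a group mostly lies in the first series, so these 2 pairs of values are not separate checks. The r within genotypes was 0.213 in AZ, 0.165 in PW, 0.268 in KP and 0.366 in TD. 50 loci were called higher in both, where independent lists of these sizes would share 10.9, and 2 were lower in both, where they would share 0.191. Unchanged groups simulated against the shared controls gave 0 in either direction. With no effect in either stress hardly any locus could be called, so that 0 does not test the overlap. With controls split between the comparisons 64 were higher and 11 lower in both, where independent lists would share 10.2 and 0.21.

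The genotypes differed in their responses to both stresses. The moderated F test called 470 loci for dehydration and 315 for heat. In dehydration the called loci had mean responses in the direction of the comparison of 2.04 in AZ, 1.89 in PW, 1.21 in TD and 0.868 in KP. limma called 904 loci in AZ, 827 in PW, 278 in TD and 129 in KP. LEA and dehydrin means were 2.56 in AZ, 2.44 in PW, 1.87 in TD and 0.84 in KP, and phosphatase means 2.60, 2.44, 1.85 and 1.42 in the same order. The F test called 4 of 7 phosphatases, 3 of 6 abscisic acid genes, 2 of 5 LEA genes (3 adjusted over the list alone), 2 of 5 DREB factors and 2 of 18 heat stress factors. For heat it called 2 of 15 small heat shock proteins, 1 of 18 heat stress factors and 1 of 6 abscisic acid genes, the last not called when adjusted over the list alone. Within the first series the mean dehydration response was 1.84 in AZ, 1.77 in PW, 0.93 in TD and 0.66 in KP, and within the second 2.25, 2.18, 1.39 and 1.38. Without the first 2 times 762 loci differed between genotypes in dehydration, without KP 221 and without AZ 289. For heat 176 differed without PW, 528 without the first library of each group and 683 within the second series.

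**Figure D3:**
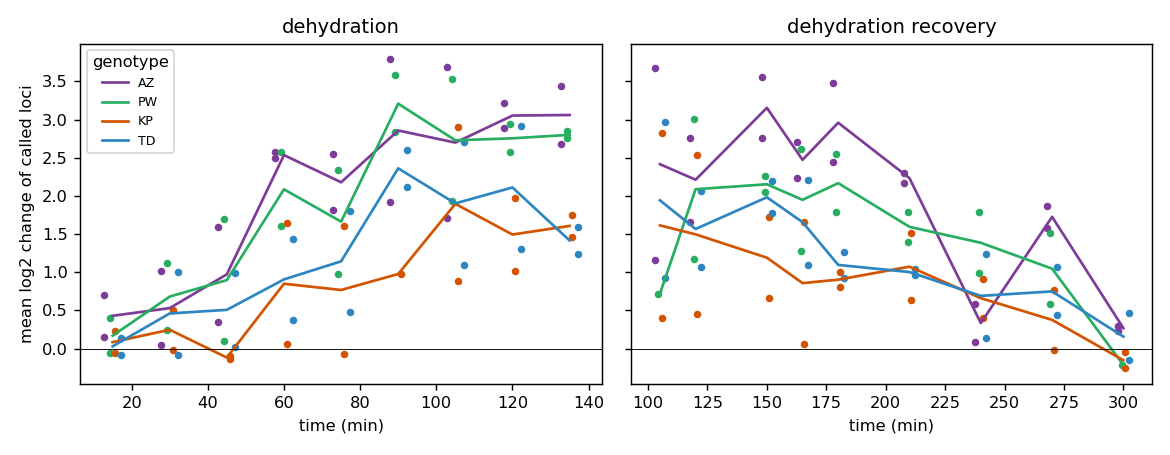
Mean log2 change of loci called in dehydration (left) and in dehydration recovery (right), in the direction of the comparison, by time in minutes, with points for single libraries and lines for the mean per genotype. Means over all times were 2.04, 1.89, 0.868 and 1.21 in dehydration and 1.98, 1.43, 0.892 and 1.21 in its recovery for AZ, PW, KP and TD, and the order differed at single times.

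In control plants, japonica (AZ and PW) and indica (KP and TD) differed at 1400 loci, 830 higher in japonica and 570 lower, whereas an adjusted p alone called 6034 higher and 6353 lower. None of the 7 lists differed (camera adjusted p 0.805 for each), although 2 of 18 heat stress factors were lower in japonica and 1 of 15 small heat shock proteins was higher. With the genotype as the unit, 2 against 2, 681 loci were called. Control levels also changed over the 18 times at 2022 loci, among them 7 of 9 clock genes and 8 of 18 heat stress factors. In a model without the interaction of genotype and time the number was 2136 with all libraries and between 3488 and 3756 with 1 library of each group left out.

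**Figure D4:**
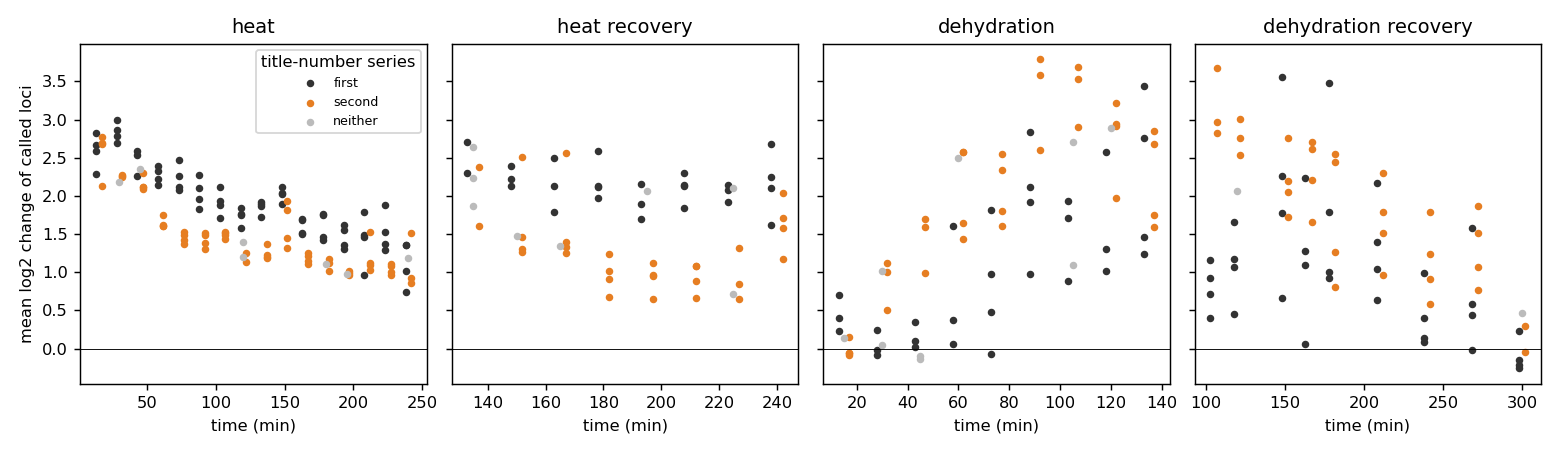
Mean log2 change of called loci in each stress library, in the direction of the comparison, by time in minutes, coloured by the series its title number falls in. In heat the first series is larger in 53 of 57 groups with 1 library of each, and in dehydration the second is larger in all but 4 of 29.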

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

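These tests were chosen or changed after the results they measure had been seen in whole or in part: the title-number series on response strength, the series and library depth on the genotype order in dehydration, library depth on the subspecies, the tests by treatment of library depth and of the 10 top loci, those on groups split by which series was higher in either, the AZ and KP comparison, and the random regroupings by genotype with each genotype's control mean removed.

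Responses differed between groups in 4 tests of the difference itself: the heat response by genotype at 315 loci, the dehydration response by genotype at 470, the late against early heat response at 523 and the late against early dehydration response at 889. Random regroupings of the libraries gave at most 204 and 287 loci for late against early heat and dehydration, where 1 of 100 splits, the real one, reached the real count. They exchanged stress and control labels within genotype and time, so chance is excluded only against no stress effect at any time. A stress effect that stays constant over time was not among them, so they do not test the late against early difference itself. For the responses by genotype a first run gave at most 465 loci for heat and 831 for dehydration, both above the real counts, and in each 4 of 100 splits, the real one included, reached the real count. Exchanging libraries between genotypes there also moves their baselines, a structure of the samples that cancels in the real comparison. With each genotype's control mean removed first, the highest other counts were 1 and 41, and 1 of 100 splits, the real one, reached the real count. The first run is therefore no test of chance for this comparison, and chance is excluded on the second alone, which was chosen after the first had been seen.

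Replicate libraries of the same stress group differed in the strength of their response. The series of title numbers were compared in groups with 1 library of each. In heat the first series had the larger response in 93% of 57 groups (means 1.92 ± 0.47 and 1.49 ± 0.48, SD over groups). In heat recovery it did in 24 of 24 (2.15 ± 0.28 and 1.21 ± 0.42). In dehydration the second had the larger one, 1.99 ± 1.10 against 1.12 ± 1.00 over 29 groups. Other heat recovery groups held a second-series library and a library in neither series. There the second-series library was larger in PW at 150 and 165 min (2.51 and 2.56 against 1.48 and 1.34) and in TD at 225 min (1.32 against 0.714). It was smaller in AZ at 195 min (0.65 against 2.06) and in TD at 135 min (1.61 against 2.23). The deeper library had the larger response in 56.2% of groups in heat, 57.1% in dehydration, 45.2% in heat recovery and 20.6% in dehydration recovery, and the library with more of its counts in its 10 top loci in 78.1%, 31.4%, 67.7% and 14.7% in the same order (the shares over all 164 groups, 47% and 53%, decide nothing, since treatments went opposite ways). The first series had the larger response in 26 of 30 heat groups where it was the shallower and 27 of 27 where it was the deeper, and in heat recovery in 12 of 12 and 12 of 12, which argues against depth in either direction there, as the share of 57.1% does in dehydration (1 of 14 and 3 of 15), but in dehydration recovery it did in 4 of 9 and 1 of 23, so a weaker response of deeper libraries stays open (two-sided exact binomial tests, the larger p of both sets adjusted over 8 such pairs, 0.000476, 0.00195, 0.0563 and 1). Where it had the lower and where it had the higher share in the top loci, it was larger in 7 of 7 and 17 of 17 groups in heat recovery (adjusted exact p 0.0417), which argues against the top loci there, and in 12 of 15 and 41 of 42 in heat, 1 of 7 and 3 of 22 in dehydration and 1 of 2 and 4 of 30 in dehydration recovery (0.0563, 0.167 and 1), where they stay open. A difference between 2 experimental runs that the title numbers follow may account for the pattern, and no biological explanation was tested because the labels name none.

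The dehydration response was larger in AZ and PW than in TD and KP. The 2 title number series with a different response strength gave the same genotype order, with a rank correlation of 1 over 4 genotypes. TD and KP were nearly equal in the second series (1.39 and 1.38). The larger response of AZ and PW in both series argues against a difference between the series as its source. It does not bear on an effect tied to genotype within a series. Library depth is argued against for AZ and KP, which had nearly equal median depth (ratio 1.001 in dehydration and 0.985 in control) and differed by 1.17 ± 0.58 (SD over 9 times, AZ larger at 9 of 9). Median totals in dehydration were 6383894.5 in PW, 6221481 in TD and 7326262 in KP, with responses of 1.89, 1.21 and 0.868. PW thus had the larger response at a lower depth than KP and a similar depth to TD. It was larger in both series (1.77 against 0.93 in TD and 0.66 in KP, and 2.18 against 1.39 and 1.38). That argues against depth for PW too. For the order of all 4 genotypes the rank correlation with median depth was 0.4, too few genotypes to decide. That the responses differ was tested above, and what sets the difference was not.

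More loci were called higher in japonica than in indica under control, but the direction depended on the fold threshold: an adjusted p alone called 6034 higher and 6353 lower (48.7% higher), and a log2 fold change of at least 2 gave 68.4% higher. Median depth was nearly equal (ratio 0.999), which argues against library depth. If reads of indica plants aligned less well to a japonica reference, an excess of loci higher in japonica would follow. The share was 59.3%, just under the bound of 60% set beforehand for this explanation, which 9 of 26 alternatives passed, among them other scalings (60.1% to 60.4%) and no filter (60.3%), and 109 of the 830 higher loci had an indica mean under 1 normalised count against 49 of 570 in the other direction. Alignment and a subspecies difference cannot be told apart here, since the build used is not given and each subspecies has 2 genotypes.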

How the results depend on the processing

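Of 366 recomputed values 301 stayed within 1.5 times the reported count (or within the spread between genotypes for the correlation) and 65 moved. A count has no sign, so directions are given apart. No count moved by over 1.5 times under other scalings (median of ratios, TMM, upper quartile), without a filter, without the 5% shallowest libraries, with a pseudocount of 10 on recovered normalised counts, in the additive model, without the repeat library, without TD, without the 105 min time, with the title-number series as a term or without the interaction of genotype and time with all libraries kept. The last 3, the pseudocount of 1, voom and the single series were chosen after seeing the data. The median of all loci in the late against early heat response was 0.04, and 0.103 under upper quartile scaling. The planned count models were not run: tests were held to the deposited log2 unit although whole counts could be recovered, and voom on those counts was run. The labels carry no replicate numbers to pair libraries by, so the series as a term is the only blocked fit. Weakly expressed loci are compressed towards the floor by the transform, and how far depth limits them was not tested. The cause of the shifts was not tested except where fewer loci or libraries explain them.

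Requiring a mean of 50 tested fewer loci and called 269 in dehydration, 178 in dehydration recovery against control, 164 against continued dehydration, 587 late against early in dehydration, 615 between subspecies, 168 and 261 by genotype in heat and dehydration, and 1281 over control times. A pseudocount of 0.25 gave 745 in heat, 284 and 446 in heat recovery against heat and control, 444 in dehydration recovery, 802 and 1356 late against early in heat and dehydration, and 625 by genotype in heat. A pseudocount of 1 gave 240 and 373 in heat recovery and 543 by genotype in heat, and voom on recovered counts 262, 406 and 496 for the same.

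An adjusted p under 0.05 alone called 13250 in heat, 10184 in dehydration, 9840 and 10511 in heat recovery against heat and control, 10691 and 2645 in dehydration recovery against control and dehydration, 13125 between stresses, 6237 and 8904 late against early, 12387 between subspecies, 4651 and 2751 by genotype and 8029 over time. A log2 fold change of at least 2 gave, in the same order, 99, 64, 4, 55, 30, 23, 146, 132, 149, 534, 41, 42 and 205.

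The majority direction of calls changed in these cases. The share higher between dehydration recovery and continued dehydration went from 35.3% to 72.5% without suffix titles, 58.4% without the first libraries and 52.5% without PW, and between heat and dehydration from 36.5% to 61% at a log2 fold change of at least 2. Under an adjusted p alone it became 46.7% in heat (62.3% reported), 47.9% in dehydration (96.4%), 54.5% and 51.7% in heat recovery against heat and control (22.9% and 40.8%), 54.8% and 48.7% late against early in heat and dehydration (6.9% and 79.4%) and 48.7% between subspecies (59.3%). Of the list means 39 changed sign, the largest at 0.334. 0 of these belonged to a list test passed at the preset correlation and 0 arose under another scaling.

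Leaving out the first or last library of each group used a model without the interaction of genotype and time, which assumes a lone library varies like the others (each series alone used it too). It gave 195 to 463 loci in dehydration recovery, 447 to 528 by genotype in heat and 3488 to 3756 over control times. Without suffix titles 120 loci were called between dehydration recovery and continued dehydration. Without AZ 165 were called in dehydration recovery and 289 by genotype in dehydration, without PW 176 by genotype in heat, without KP 221 by genotype in dehydration, and without the first 2 times 762 by genotype in dehydration. With the genotype as the unit 681 differed between subspecies. The first series alone gave 3113 over control times. The second alone gave 679 in dehydration, 664 in its recovery, 1497 late against early in dehydration, 683 by genotype in heat and 3428 over control times, and gave no value for dehydration recovery against continued dehydration, where pairs were missing. Of 26 list tests passed at a preset correlation, 10 passed with an estimated one.

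Random regroupings gave at most 11 loci for heat, 28 for dehydration, 2 and 6 for heat recovery against heat and control, 7 for dehydration recovery against control, 31 between stresses and 308 over control times, and in each 1 of 100 splits, the real one, reached the real count, so chance can be excluded. For dehydration recovery against continued dehydration 4 of 100 splits, the real one included, reached 278, the highest other 390. That share is under 0.05 but is not adjusted over the comparisons regrouped, so chance is not firmly excluded. For subspecies, set by genotype, the 3 splits of the 4 genotypes, a test chosen after seeing the data, are too few for a share under 0.05; the real one, 1 of 3 to reach its count, gave 1400 and the highest other 515. Swaps between dehydration recovery and continued dehydration can follow the title-number series, and with the series as a term 274 loci were called in that comparison. That fit keeps the fold changes of groups with 1 library of each series, so the 274 loci do not decide the matter.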

Other observations

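Heat stress transcription factors had a mean of -0.02 ± 0.22 against control at 135 min of heat recovery and -0.46 ± 0.31 at 210 min (SD over 4 genotypes), while small heat shock proteins stood at 4.34 ± 0.26 and 2.56 ± 0.51 at the same times. In continued heat the factor mean was 0.42 ± 0.26 at 135 min. LEA proteins and dehydrins had no steady course in heat, with means of 3.26 ± 0.65 at 15 min, -0.01 ± 0.42 at 75 min, 2.77 ± 1.11 at 150 min, 2.10 ± 0.77 at 225 min and -0.43 ± 1.68 at 240 min. Against the same control libraries the mean at 240 min was also low in heat recovery, -0.40 ± 1.24 after 1.10 at 225 min. In dehydration recovery it was 0.48 ± 1.48 at 240 min, after 2.91 at 210 min and before 1.44 at 270 min. The drop at 240 min can therefore lie in the shared controls and cannot be assigned to heat. In dehydration the SD of the LEA and dehydrin mean over genotypes was 0.058 at 15 min, 2.07 at 90 min, 0.56 at 105 min and 1.77 at 120 min.

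The comparison of title-number series was chosen after the data were seen. Loci that differed between the 2 series within control, on paired differences of 57 groups, numbered 1 higher in the first and 26 higher in the second by limma. The numbers were 24 and 74 in heat, 20 and 230 in dehydration, 21 and 80 in heat recovery and 78 and 121 in dehydration recovery.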
